A study of Mus musculus with 2 samples.

How the data were processed

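RNA-seq values of 2 biological replicates of mouse central nervous system at embryonic day 14 were analysed as 1 group, with the replicate numbers taken from the labels. The labels name separate biosamples of pooled male and female littermates under a shared donor identifier, so the spread between replicates is that of 2 pools. Per the labels, the libraries are stranded and paired-end, from poly(A)+ RNA depleted of ribosomal RNA. The deposited tables give expected counts, TPM and FPKM per gene on mm10 with GENCODE M4, per the text deposited with them. Expected counts are estimates that need not be whole (of genes above 0, 88.3% and 87.7% were listed with exactly whole values), the deposited TPM are shares of transcripts over all features, spike-ins included, and the deposited FPKM are scaled by effective length and by the number of fragments. The deposited transcript tables give TPM and the percent of the gene's TPM in each transcript. The aligner and the quantifier are not given in the sources used here.

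On mm9, the deposited gene tables give RPKM in 2 fields, for Ensembl release 65 genes and, per the file contents, for gene models assembled with Cufflinks. The deposited junction table gives the read count of each splice junction in 2 fields, and the deposited contig table was read as coverage, from its values, since it has no header. The Ensembl gene table lists each gene in 2 lines, and its 74620 lines were reduced to 37310 genes. The fields of the mm9 tables are not matched to the numbered replicates by any label, so they are called field 1 and field 2. They were compared with mm10 as means over both, as differences between fields whose direction was not read, and in a check of field order. The mm9 tables of assembled exons, assembled transcripts and annotated transcripts were not used.

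The mm10 tables held 69691 features, of which 43346 were genes, 97 were spike-in or control sequences and 26248 were features named by number, with 1 and 5 counts, which were left out of library sizes. Gene symbols and positions were taken from GENCODE M21 on the same build by stable identifier, which matched 42462 genes; 20 symbols stood on several identifiers. Of the listed genes, Ahsp, Drgx, Sox2ot, Rmst and Peg13 were not matched and were not analysed here. Total expected counts were 102727538 and 138440954. A count of 0 allows up to 3 counts, or 0.0301 and 0.0223 CPM in replicates 1 and 2. Intervals are exact 95% intervals and, like these floors, cover counting error only, since reads without molecular identifiers are not independent molecules.

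The 39 gene lists, with 483 genes in all, the rule for named genes, the tests and a first set of alternatives were fixed before the data were examined. The rule names from each list the 4 members with the highest mean TPM and the lowest, all genes with known isoform differences, the 10 most abundant genes that are not mitochondrially encoded, and the 5 protein-coding genes with the largest and the 5 with the smallest log2 ratio among those with a mean expected count of at least 200. A few genes that the rule names are not reported here. The number of genes at least 2-fold apart was counted after the data had been seen. Genes were called detected at 1 TPM, and differences of list medians were taken on the log2(TPM + 1) scale, which understates changes of low genes. Replicates were compared on expected counts rounded to whole numbers, scaled by TMM with a prior count of 1. With a single library for each replicate there is no p-value. A list's median log2 ratio was instead placed among 10000 random lists of the same size drawn from genes of similar mean expression. The common dispersion was estimated with edgeR 4.0.16 in R 4.3.3 after its filter on low counts, and DESeq2 1.42.0 gave alternative size factors and dispersion. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, regions with bedtools 2.31.1, and figures were drawn with matplotlib 3.10.9.

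Both statistics across many genes were tested on simulated data. With a set coefficient of variation of 0.1 and 0.3 over 18821 genes, 0.129 and 0.304 were recovered. Over 19513 genes, with 2000 random lists, 9 of 10 lists changed 2-fold and 10 of 10 changed 4-fold lay outside the range, and so did 21 of 300 unchanged lists (7.00%). The alternatives were other pseudocounts, thresholds and filters, FPKM or TMM-scaled CPM in place of TPM, the mm9 RPKM, TPM without mitochondrial genes and spike-ins, other scalings, matching on gene length, and each replicate alone.

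Several properties of the processing bear on the values. TPM depends on an effective length that is close to 0 for short genes, and it was listed as 0 for 5458 and 5131 genes, so that a TPM of 0 in a short gene does not show absence. Length exceeded effective length by 197 nucleotides in replicate 1 and 187 in replicate 2. Selection of poly(A)+ RNA lowers transcripts without a tail, and reads that fit several near-identical copies are divided by estimation.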

Results

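Gene expression was measured in central nervous system tissue of C57BL/6J mouse embryos at embryonic day 14. At this age progenitors lining the ventricles are still dividing and much of the tissue consists of young neurons. The labels describe 1 group with 2 biological replicates, numbered 1 and 2, each made from pooled male and female littermates. Stranded paired-end libraries were made from poly(A)+ RNA longer than 200 nucleotides after depletion of ribosomal RNA, and ERCC spike-in RNAs were added. The deposited mm10 gene tables held 102727538 expected counts in replicate 1 and 138440954 in replicate 2, of which 99528934 and 134760822 belonged to genes. The spike-ins took 2.45% and 2.35% of the counts, and mitochondrially encoded genes took 1.54% and 1.67% of the counts of genes. With a single group there is no contrast between conditions, so the comparisons are between gene groups within the tissue and between the replicates. Values are given as mean ± SD over n = 2 replicates, or for replicate 1 and replicate 2 in that order, and gene positions refer to mm10.

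Transcripts of 15005 of 43346 genes reached 1 TPM in both replicates, with 691 more in replicate 1 alone and 264 more in replicate 2 alone. Of 21474 protein-coding genes, 13609 (63.4%) reached that level in both, against 231 of 2777 long intergenic non-coding RNA genes. Leaving out the mitochondrially encoded genes, the 10 most abundant transcripts included those of the tubulins Tuba1a (chromosome 15, 98949837 to 98953703), at 8860 ± 619 TPM, and Tubb2b, at 6492 ± 986 TPM, which build the microtubules of growing neurites. The small nuclear RNA Rn7sk stood between these at 6888 and 9144 TPM, the translation factor Eef1a1 at 6401 ± 18.1 TPM, the ribosomal protein genes Rplp1 and Rps12 at 4900 ± 71.4 and 4101 ± 265 TPM, and the ubiquitin gene Ubb at 3619 ± 403 TPM. Nnat, an imprinted gene expressed in young neurons, had 5525 ± 432 TPM. Gm42418 (5567 TPM on average) and Gm29216 (4524 TPM) completed these 10, and these, the tubulins and the ribosomal protein genes can share reads with near-identical copies, so their levels are uncertain.

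Neuronal genes were the most strongly expressed of the cell type groups that belong to nervous tissue. All 20 genes listed for postmitotic neurons were detected (mean of at least 1 TPM), with a median of 168 ± 14.5 TPM. They were led by Tubb3 (chromosome 8, 123411424 to 123422015), the neuronal tubulin, at 1977 ± 222 TPM, the growth cone gene Gap43 at 716 ± 65 TPM, Dpysl3 at 647 ± 46.8 TPM and Stmn2 at 605 ± 2.13 TPM. Rbfox3, a marker of more mature neurons, was the lowest at 24.8 ± 0.453 TPM. Genes of radial glia and neural progenitors were all detected as well (20 of 20), with a median of 48.5 ± 6.48 TPM. Vim (chromosome 2, 13573927 to 13582826) reached 937 ± 34.2 TPM, Fabp7, a lipid-binding protein of radial glia, 917 TPM on average, Dbi 565 ± 119 TPM and the RNA-binding protein gene Msi1 188 ± 32.6 TPM, while Lin28b stood at 8.46 ± 0.431 TPM.

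The medians of these lists on the log2(TPM + 1) scale differed by 1.82 in replicate 1 and 1.73 in replicate 2, neurons above radial glia (1.78 ± 0.06). The difference was far larger than its spread between replicates, which measures only how well these lists repeat. Its size also depends on the genes listed and on the unit (2.32 in TMM-scaled CPM). An exact test on 2 values cannot reach 0.05 and none was run. All 21 cell cycle genes were detected with a median of 58.3 ± 8.73 TPM, from Pcna at 205 ± 39.5 TPM, Cdk1 at 160 ± 27.7 TPM and Ube2c at 141 ± 30.5 TPM down to Bub1 at 17.8 ± 4.82 TPM. Of 16 genes of intermediate progenitors and proneural factors, 15 were detected (median 38.9 ± 11.8 TPM). Hes6 (140 ± 23.2 TPM) and Gadd45g (112 ± 22.0 TPM) were among the highest, and Ptf1a, a factor of inhibitory lineages of the hindbrain and cord, was below 1 TPM (0.445 ± 0.134).

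**Figure D1:**
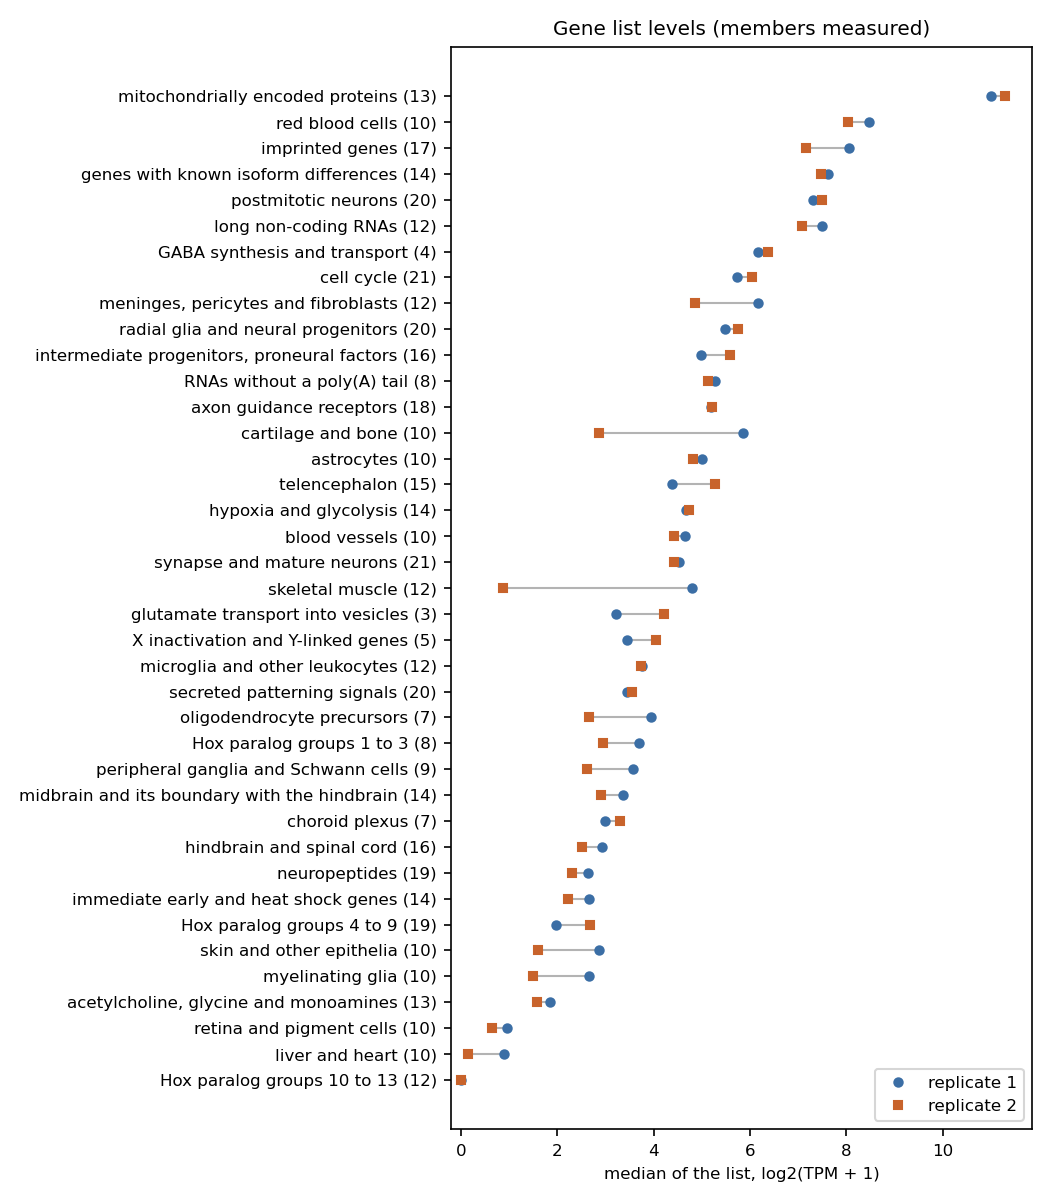
Median level of each gene list on the log2(TPM + 1) scale, with replicate 1 as circles, replicate 2 as squares, a line joining the replicates and the number of measured members in parentheses. Mitochondrially encoded genes stand highest, neuronal genes lie above radial glia in both replicates, and the widest gaps between replicates are those of skeletal muscle and of cartilage and bone.

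Genes of synapses and mature neurons were present at lower levels (20 of 21 detected, median 21.2 ± 1.17 TPM). The vesicle proteins Vamp2 and Syp had 208 ± 17 and 142 ± 11.1 TPM and the postsynaptic genes Dlg4 and Gria2 had 178 ± 6.58 and 137 ± 29.6 TPM, whereas Grin2a, a glutamate receptor subunit of the postnatal brain, had 0.670 ± 0.0141 TPM. For transmitters, the summed TPM of the 3 vesicular glutamate transporters was compared with that of Gad1, Gad2 and Slc32a1, which make GABA and load it into vesicles. The log2 ratio was -2.31 and -2.10 (-2.20 ± 0.15), so the glutamatergic sum was the lower in both replicates. Only the GABA sum includes synthesis enzymes. Between transporters alone the gap was small, with 37.3 and 45.9 TPM for the 3 glutamate transporters and 49.9 and 52.2 TPM for Slc32a1. Slc17a6 had 27.1 ± 0.0424 TPM, Slc17a7 8.27 and 17.5 TPM and Slc17a8 1.58 ± 0.495 TPM, for a list median of 12.9 ± 6.51 TPM with 3 of 3 detected. Gad1 (chromosome 2, 70553072 to 70602014) had 108 ± 3.77 TPM, Slc32a1 51.0 ± 1.61 TPM and Gad2 31.5 ± 3.17 TPM, for a GABA list median of 76.3 ± 7.23 TPM with 4 of 4 detected. These are amounts of RNA per transcript, not numbers of cells.

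Genes of acetylcholine, glycine and monoamine neurons were low (11 of 13 detected, median 2.30 ± 0.424 TPM), with the vesicular monoamine transporter Slc18a2 at 20.6 ± 6.42 TPM, the catecholamine enzyme Th at 13.3 ± 4.25 TPM and Chat, which makes acetylcholine, at 0.820 ± 0.283 TPM. Of 19 neuropeptide genes, 16 were detected (median 4.59 ± 0.940 TPM), led by Sst (157 ± 14.8 TPM) and Npy (81.5 ± 9.27 TPM), while Oxt had 8 counts in replicate 1 and 1 in replicate 2. All 18 axon guidance receptor genes were detected (median 35.7 ± 0.276 TPM), with Plxna1 at 74.6 ± 0.233 TPM and Robo2 at 73.7 ± 9.61 TPM. Of 20 secreted patterning signals, 18 were detected (median 10.3 ± 0.544 TPM), with the chemokine gene Cxcl12 at 85.2 ± 14.8 TPM, Reln, which guides migrating neurons, at 73.6 ± 20.1 TPM, and the roof plate gene Gdf7 at 0.535 ± 0.332 TPM.

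Regional genes showed forebrain, midbrain, hindbrain and cord in the same tissue. All 15 telencephalon genes were detected (median 28.6 ± 12.5 TPM), among them Lhx2 (chromosome 2, 38339281 to 38369733) at 205 ± 77.9 TPM and Dlx1 at 108 ± 51.3 TPM. All 14 genes of the midbrain and its boundary with the hindbrain were detected (median 7.89 ± 1.91 TPM), with Otx2 at 36.5 ± 2.23 TPM and En2 at 17.5 ± 4.23 TPM, and 12 of 16 genes of hindbrain and cord (median 5.67 ± 1.38 TPM), with Foxp1 at 45.7 ± 3.30 TPM and Mnx1, a motor neuron factor, at 0.145 ± 0.0212 TPM. Hox genes mark position along the hindbrain and cord. Paralog groups 1 to 3 had 6 of 8 genes detected (median 9.32 ± 3.69 TPM), groups 4 to 9 had 16 of 19 (median 4.18 ± 1.78 TPM), and groups 10 to 13 had 0 of 12, with 38 counts in all in replicate 1 and 24 in replicate 2. The telencephalon median exceeded that of Hox groups 4 to 9 by 2.40 and 2.58 on the log2(TPM + 1) scale (2.49 ± 0.12), and by 1.46 in the deposited mm9 RPKM values.

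Genes of glia ranged from abundant to barely detected. Of 10 astrocyte genes 8 were detected (median 29.2 ± 2.79 TPM), with Apoe (262 ± 0.474 TPM) and the glutamine synthetase gene Glul (173 ± 4.97 TPM) highest, both of which other cells also express, and Gfap at 0.445 ± 0.163 TPM. All 7 genes of oligodendrocyte precursors were detected (median 9.83 ± 6.34 TPM), with Olig1 at 26.4 ± 2.91 TPM and Olig2 at 15.3 ± 1.44 TPM. Of 10 myelin genes 6 were detected (median 3.55 ± 2.44 TPM), with Mbp at 12.6 ± 0.863 TPM, while Opalin, a gene of mature oligodendrocytes, had 1 and 3 counts.

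Genes of vessels, blood and immune cells accompanied the neural ones. All 10 genes of blood vessels were detected (median 22.3 ± 2.45 TPM), with Egfl7 at 153 ± 15.9 TPM and Cldn5, a tight junction gene of brain endothelium, at 77.4 ± 2.55 TPM. All 12 genes of microglia and other leukocytes were detected (median 12.4 ± 0.184 TPM), with C1qb at 29.3 ± 2.91 TPM and Ptprc at 1.54 ± 0.0990 TPM. Red blood cell genes had 9 of 10 detected (median 306 ± 65.1 TPM), and the adult globin genes Hba-a2 (4522 and 2161 TPM) and Hbb-bs (3820 and 1897 TPM) were the highest, with reads that near-identical globin copies can share. Choroid plexus genes had 6 of 7 detected (median 7.88 ± 1.35 TPM), and Ttr (chromosome 18, 20665280 to 20674321), the thyroid hormone carrier made by that epithelium, stood out at 1211 ± 299 TPM. Retina and pigment cell genes had 5 of 10 detected (median 0.75 ± 0.276 TPM), with Rlbp1 at 26.8 ± 10.2 TPM and the lens gene Cryaa at 1 and 0 counts.

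Tissues outside the nervous system were represented too. All 12 genes of meninges, pericytes and fibroblasts (median 49.2 ± 30.2 TPM), all 12 of skeletal muscle (13.8 ± 18.3 TPM), all 10 of cartilage and bone (31.5 ± 35.7 TPM), all 10 of skin and other epithelia (4.15 ± 3.01 TPM) and all 9 of peripheral ganglia and Schwann cells (7.98 ± 4.06 TPM) were detected by their mean. Of 10 liver and heart genes, 4 were detected (0.475 ± 0.530 TPM). In replicate 2 alone, 4 of the 12 muscle genes and 2 of the 10 liver and heart genes reached 1 TPM.

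All 17 imprinted genes were detected (median 205 ± 87.4 TPM), headed by Nnat, Meg3 (4198 and 2978 TPM), H19 (1976 and 544 TPM) and Ndn (739 ± 7.65 TPM). Of 12 long non-coding RNAs 11 were detected (median 157 ± 32.7 TPM), with Gas5 at 1119 ± 25.2 TPM, Miat, which is abundant in neurons, at 638 ± 17 TPM and Malat1 at 489 ± 17.9 TPM, and Kcnq1ot1 at 0.980 ± 0.113 TPM. RNAs without a poly(A) tail had 4 of 8 detected (median 35.8 ± 2.35 TPM), among them Scarna2 at 358 ± 30.8 TPM and Rmrp at 239 ± 4.38 TPM. Rny3 had 0 counts in both libraries, where 3 counts correspond to 0.0301 and 0.0223 CPM; it spans less than the size limit of 200 nucleotides. All 13 mitochondrially encoded protein genes were detected (median 2286 ± 313 TPM), with mt-Co1 at 5424 ± 539 TPM and mt-Nd6 at 404 ± 26.8 TPM. The highest value, mt-Atp8 at 37810 and 20894 TPM, rests on an effective length of 15.1 and 21.4 nucleotides for a gene of 204 nucleotides, and the same gene had only 363 and 279 CPM.

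Of the immediate early and heat shock genes 13 of 14 were detected (median 4.48 ± 1.20 TPM), with the constitutive chaperone gene Hspa8 far above the rest (2759 ± 564 TPM), while Jun had 41.0 ± 3.28 TPM and Fosb 0.125 ± 0.0919 TPM. Hypoxia and glycolysis genes had 13 of 14 detected (median 25.1 ± 0.693 TPM), with the glycolytic genes Eno1 at 374 ± 0.544 TPM and Ldha at 300.4 ± 18.3 TPM, and Car9, a hypoxia target, at 0.545 ± 0.163 TPM. All 14 genes chosen for known isoform differences were detected (median 186 ± 13.9 TPM).

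Most genes had similar levels in the replicates, and the exceptions lay largely on one side. Among 14340 genes with a mean expected count of at least 200, the median absolute log2 ratio was 0.14, and 580 genes were at least 2-fold lower and 40 at least 2-fold higher in replicate 2 than in replicate 1. Among protein-coding genes of that abundance, the lowest in replicate 2 were Col10a1, a collagen of hypertrophic cartilage (19.5 and 0.0400 TPM), the muscle genes Ckm, Tnnc2 and Myh3 (log2 ratios of -7.90, -6.67 and -6.56) and Oc90, a gene of the inner ear (56.0 and 0.310 TPM). The highest of them were 4 Hox genes, Hoxc8, Hoxb9, Hoxa7 and Hoxc6, and Gm3194, which belongs to a family of similar genes and is uncertain (log2 ratio 5.84). On the log2(TPM + 1) scale 407 genes in all were at least 2-fold apart instead of 620, and with a pseudocount of 0.01 TPM, which shrinks the ratios of low genes less, 603 were. These are differences between 1 library and 1 library of the same group, with no p-value.

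Across all genes, log2(TPM + 1) correlated between replicates with Pearson r = 0.992 and Spearman rho = 0.965; genes are not independent replicates. The common biological coefficient of variation was 25.3% over 18821 genes in edgeR, and 15.4% as the median of DESeq2's fitted trend over the same number of genes. The counts differed by more than sampling noise (chi-square of 141 per degree of freedom over 19513 genes), so they were not the same library listed again; that they are separate biological replicates comes from the labels. The 47 ERCC spike-ins with enough counts had a median absolute deviation of 0.07 in log2 ratio, against 0.14 for genes.

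**Figure D2:**
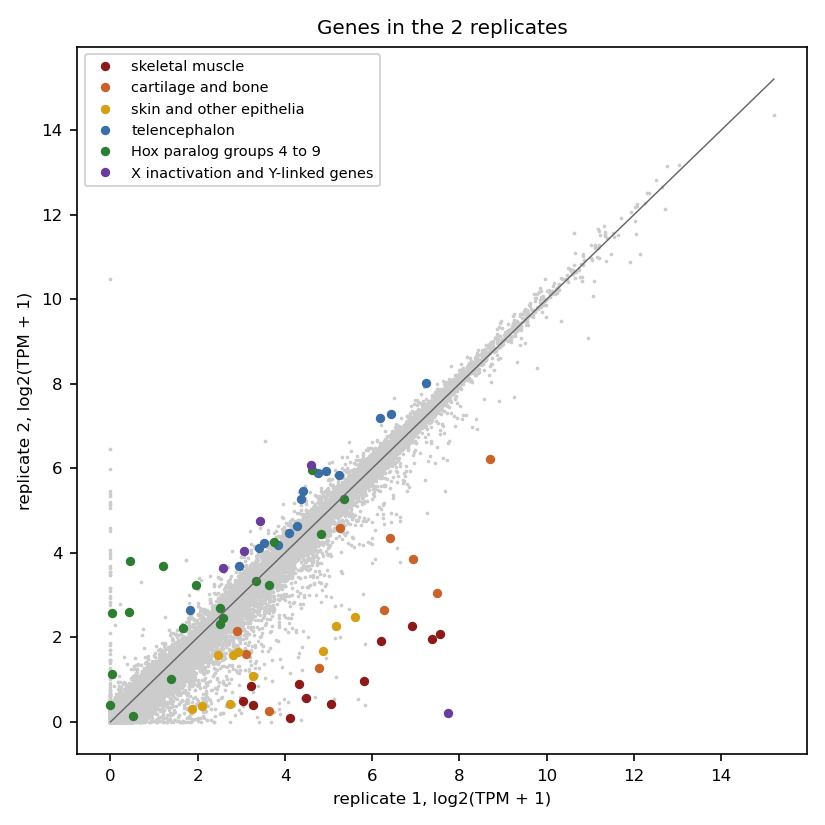
Each gene in replicate 1 (horizontal axis) and replicate 2 (vertical axis) on the log2(TPM + 1) scale, with the line of equal level and members of 6 gene lists in colour. Muscle, cartilage and epithelial genes lie below the line, all 15 telencephalon genes above it, and the purple point at the lower right is Xist, at 214 and 0.150 TPM.

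Gene groups of tissues outside the nervous system were lower in replicate 2. All 12 skeletal muscle genes were at least 2-fold lower there (median log2 ratio -5.20), as were all 10 genes of skin and other epithelia (-3.28) and 8 of 10 of cartilage and bone (-2.91). Actc1 (chromosome 2, 114047282 to 114053548), the actin of embryonic and heart muscle, had 186 and 3.26 TPM, the myosin light chain gene Mylpf 163 and 2.87 TPM and the skeletal actin gene Acta1 119 and 3.81 TPM. Col2a1 (chromosome 15, 97975602 to 98004695), the main collagen of cartilage, had 417 and 73.5 TPM and Matn1 177 and 7.34 TPM. The basal keratin genes Krt5 (chromosome 15, 101707070 to 101712898) and Krt14 had 48.0 and 4.61 TPM, and 34.8 and 3.82 TPM.

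The same direction held, less steeply, for peripheral ganglia and Schwann cells (median log2 ratio -1.67, 6 of 9 genes at least 2-fold lower), with the peripheral neuron filament gene Prph at 93.1 and 29.4 TPM, and for meninges, pericytes and fibroblasts (-1.0, 6 of 12), with the collagen gene Col3a1 at 339 and 121 TPM. Liver and heart genes were also lower (-0.88, 5 of 10), and 2 of these, Ttn and Myh7 (log2 ratios of -5.24 and -2.59), are also genes of skeletal muscle. Imprinted genes had a median of -0.67, with H19 at -1.86, and red blood cell genes -0.64, with all 10 below 0. Oligodendrocyte precursor genes had -0.54; 3 of the 7 were at least 2-fold lower, among them Sox10 (16.8 and 4.84 TPM), which neural crest and Schwann cells also express, and Pdgfra (22.7 and 8.48 TPM), which fibroblasts also express, while Olig2 had a ratio of 0.18.

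Progenitor and forebrain genes were higher in replicate 2. All 15 telencephalon genes lay above 0 (median log2 ratio 0.81), with Lhx2 at 150 and 260.3 TPM and Dlx1 at 71.6 and 144 TPM. Genes of intermediate progenitors and proneural factors followed (0.60, 14 of 16 above 0), with Neurod6, a gene of young excitatory neurons of the cortex, at 89.0 and 203 TPM and Neurog2 (chromosome 3, 127633135 to 127635631), a proneural factor, at 43.1 and 97.1 TPM. Cell cycle genes (0.37, 20 of 21 above 0), choroid plexus genes (0.34) and radial glia genes (0.28, 16 of 20 above 0) were higher by less. Genes of hindbrain and cord (-0.46), midbrain (-0.42) and acetylcholine, glycine and monoamine neurons (-0.49, 12 of 13 below 0) were lower in replicate 2.

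Altogether 24 of the 39 lists had a median outside the central 95% of 10000 random lists of the same size matched on mean expression. Of these, 16 lay below and 8 above it. Nominally 1.95 of 39 would fall outside, and 21 of 300 unchanged lists did so in simulated data. Both numbers take genes as varying independently, while members of a list can vary together, so neither is the chance rate for these lists. Lists also share genes and are not independent. Among those outside were also long non-coding RNAs (-0.28), blood vessels (-0.14), neurons (-0.01, at percentile 2.10, and 0.01 or 0.04 under DESeq2 or spike-in scaling, still below the range) and neuropeptides (0.12, with a mean of -0.22 of the opposite sign). In TPM, with a pseudocount of 1 or 0.01, the medians of neurons and neuropeptides were no longer outside and those of astrocytes and microglia were; blood vessels came inside and myelinating glia went outside only with 1, and choroid plexus came inside and retina and pigment cells went outside only with 0.01. Neuropeptides also came inside, and myelinating glia went outside, over members with at least 50 counts, and neuropeptides came inside with matching on gene length.

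Inside the range were genes of synapses and mature neurons (-0.02), astrocytes (-0.10), myelinating glia (-0.26), microglia and other leukocytes (0.11), retina and pigment cells (-0.48), Hox groups 10 to 13 (-1.26, over 4 genes with any count), glutamate transport (-0.01), GABA synthesis and transport (0.13), patterning signals (-0.14), axon guidance receptors (0.06), RNAs without a poly(A) tail (0.22), mitochondrially encoded proteins (0.16), immediate early and heat shock genes (-0.21), hypoxia and glycolysis (0.07) and genes with known isoform differences (0.02). A median inside the range does not show that the levels were equal.

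**Figure D3:**
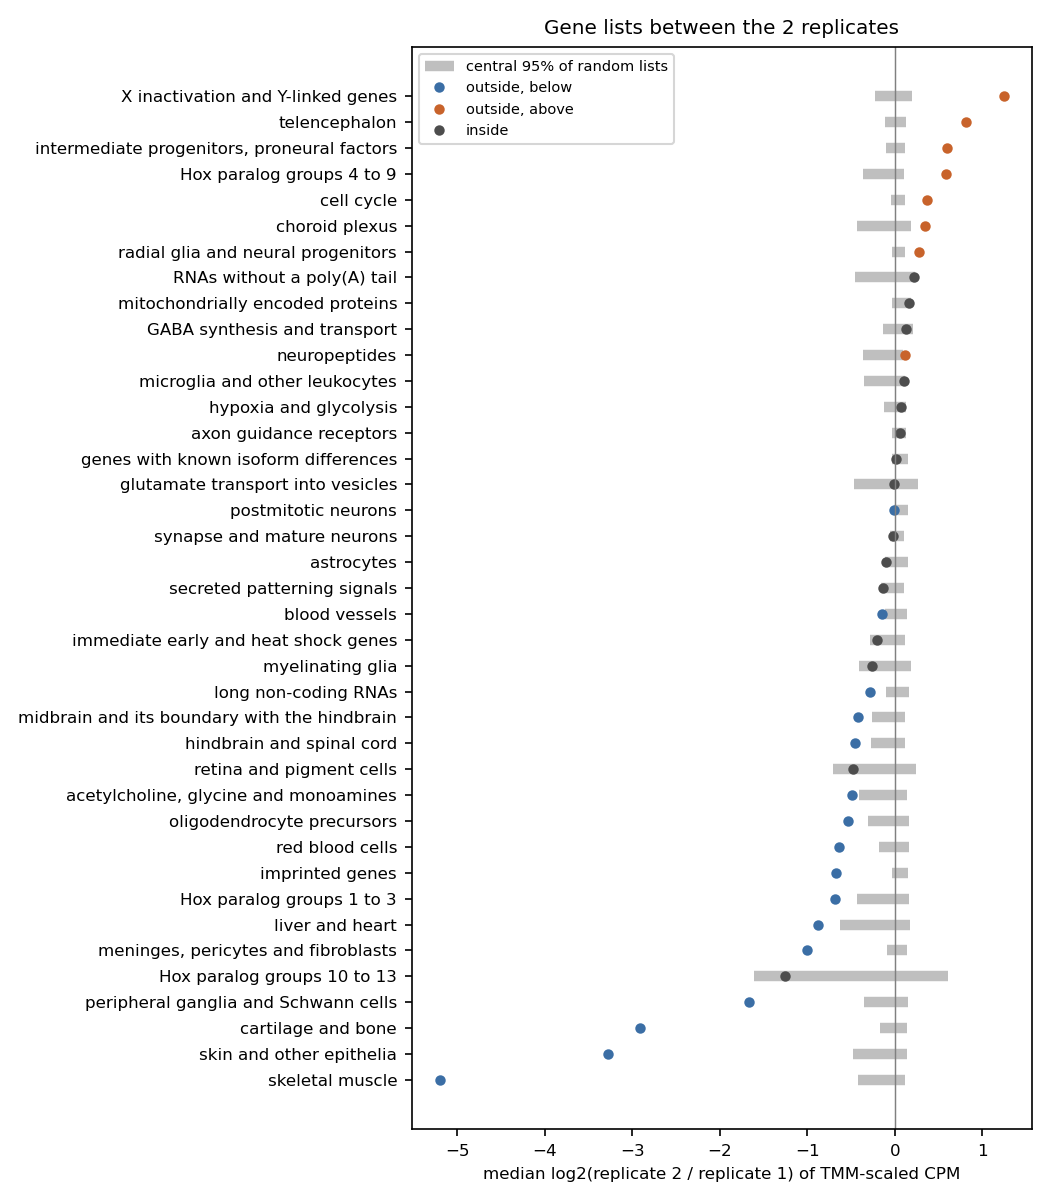
Median log2 ratio of each gene list between the replicates (TMM-scaled CPM, replicate 2 over replicate 1), as a point, with a grey bar over the central 95% of 10000 matched random lists. Skeletal muscle lies lowest at -5.20, and 8 lists, shown in orange, lie above their bars.

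Hox genes differed between the replicates according to their paralog group. All 8 genes of groups 1 to 3 were lower in replicate 2 (median log2 ratio -0.69), such as Hoxa2 (13.7 and 6.39 TPM) and Hoxd3 (30.3 and 17.4 TPM). Of the 19 genes of groups 4 to 9, 12 were higher (median 0.59, mean 1.68), among them Hoxc8 (chromosome 15, 102990607 to 102994111), with 2 and 721 counts, a log2 ratio of 7.56 and a 95% interval of 6.21 to 11.12, and Hoxb9 (0.360 and 13.1 TPM), while the abundant Hoxb8 (chromosome 11, 96281905 to 96285315) had 23.6 and 61.0 TPM and Hoxa5 39.8 and 37.6 TPM. Hoxc9 had 0 and 58 counts. Summed over genes, group 5 had 72.0 and 63.7 TPM, group 6 15.9 and 33.5 TPM, group 8 25.2 and 67.0 TPM and group 9 0.8 and 14.7 TPM. The Hoxd genes of groups 8 and 9, named after their values were seen, went the other way: Hoxd8 had 1.61 and 1.01 TPM and Hoxd9 0.420 and 0.110 TPM.

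**Figure D4:**
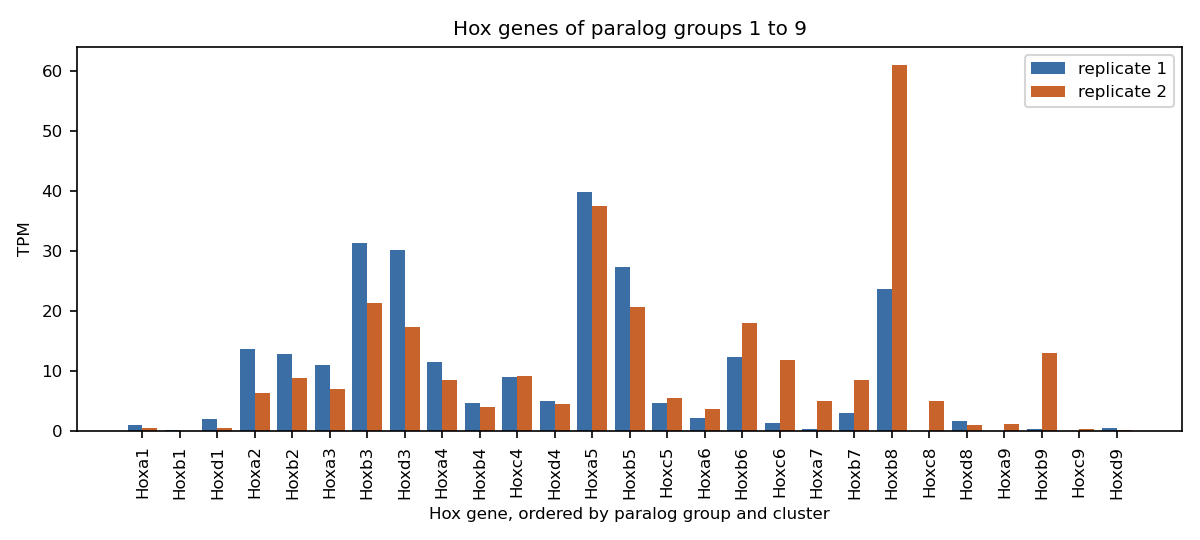
Level in TPM of the Hox genes of paralog groups 1 to 9, ordered by group and then by cluster, with a bar for each replicate. Replicate 1 is higher in groups 1 to 3 and replicate 2 in most genes of groups 6 to 9, with Hoxb8 at 23.6 and 61.0 TPM.

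Genes tied to sex differed strongly although the labels give pooled male and female embryos for both replicates. Xist (chromosome X, 103460366 to 103483254), the non-coding RNA that silences an X chromosome in female cells, had 122314 counts in replicate 1 and 94 in replicate 2, or 214 and 0.150 TPM. All 4 Y-linked genes were higher in replicate 2, namely Eif2s3y (23.3 and 66.4 TPM), Kdm5d (9.84 and 25.9 TPM), Ddx3y (7.31 and 15.4 TPM) and Uty (5.00 and 11.6 TPM). The list of these 5 genes (5 of 5 detected, median 12.6 ± 3.96 TPM) had a median log2 ratio of 1.25 and, through Xist, a mean of -1.08.

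In the transcript tables, the most abundant transcript was the same in both replicates for 9764 of 10392 genes (94.0%) with at least 1 TPM in both and several annotated transcripts. Among the genes with known isoform differences, Pkm, a glycolytic enzyme with a pair of alternative forms, had 62.5% ± 3.34 of its TPM in Pkm-201 and 37.5% ± 3.34 in Pkm-202. Cdc42 was split into 52.0% ± 1.77 and 48.0% ± 1.77, and Clta, a clathrin light chain gene, had 54.6% ± 2.32 in Clta-204. The largest share of Ncam1, a neural adhesion molecule, was 43.1% ± 2.41, and those of Map2, Gria2 and Numb were 41.9% ± 0.247, 23.7% ± 2.43 and 37.6% ± 2.38. Dlg4 had 57.0% ± 2.13 in a coding transcript. The top transcripts of Ptbp1 (33.9% ± 0.148, a retained intron) and Pax6 (26.6% ± 3.96, a processed transcript) were not annotated as coding. Mapt, which encodes tau, had 96.2% ± 0.332 in Mapt-204, which carries a 93-nucleotide exon that junction reads on mm9 included in only 3.21%; the coding transcripts without it have at most 6 exons, so this share does not measure use of the exon. The tables held a single transcript for App and for Ptbp2.

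The authors also deposited values of the same study on the mm9 build, and these were compared with the mm10 values. Across 33068 shared genes, the mean mm9 RPKM and the mean mm10 FPKM correlated with Pearson r = 0.909 and Spearman rho = 0.948 on the log2(value + 1) scale. In the mm9 gene table, 10633 genes had at least 1 RPKM in both of its fields, and 296 of the list genes had a mean of at least 1 RPKM there, against 423 with at least 1 TPM in the mm10 tables, which are different units. Of the 13 mitochondrially encoded genes, which are abundant on mm10, 0 reached 1 RPKM on mm9, so low mm9 values do not show absence. The mm9 fields are not assigned to the numbered replicates here.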

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

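All of these values were chosen for a closer look after the data were seen, and each is a signal in sequences or tables that the comparisons did not use; no explanation was tested for them. The control genome phiX174 had 684619 expected counts in replicate 1 (0.666%) and 425968 in replicate 2 (0.308%). Of 1302067 splice junctions on mm9, 61.3% rested on a single read and Ensembl 65 introns held 95.4% of all junction reads, while 18967 junctions outside those introns had at least 10 reads in both fields (34192 at 5 reads and 4513 at 50). Of 49668 assembled gene models without an annotated gene, 202 had at least 1 RPKM in both fields (333 at 0.5 and 46 at 5 RPKM), the highest on chromosome 11 of mm9 from 108872954 to 108873498, with 727 ± 97.2 RPKM (SD over 2 fields). Contigs that touch no annotated gene held 3.63% of contig coverage, and 11.3% when a contig counted as outside unless a gene covered 50 percent of it.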

How the results depend on the processing

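No list median outside its range and none of the 620 genes 2-fold apart changed sign in TPM. The DESeq2 and spike-in scalings move all genes alike by 0.02 and 0.05. Of these values, they turned only the median of neurons (-0.01, but 0.01 and 0.04). Alternatives for exon inclusion, junctions, models, contigs, named gene ratios and genes 2-fold apart, and the ERCC, mm9 and 0.01 TPM settings for list shifts, were chosen after seeing the data. Either replicate alone gave 15269 to 15696 detected genes, 405 to 426 detected list genes, and differences of 1.73 to 1.82 (neurons and radial glia), 2.40 to 2.58 (telencephalon and Hox) and -2.31 to -2.10 (transmitters). The replicate correlation was 0.990 with a pseudocount of 0.1 and 0.972 over genes of at least 1 TPM. The coefficient of variation was 25.2% with DESeq2 size factors, 29.4% without the filter and 15.4% from DESeq2's trend, and the chi-square 175 from 100 counts. Neurons and radial glia differed by 2.32 in CPM and 1.70 on mm9. Telencephalon and Hox differed by 2.74 (pseudocount 0.1), 2.35 (FPKM), 2.94 (CPM) and 1.46 (mm9), and the transmitter ratio was -1.63 in CPM. Genes 2-fold apart numbered 407 in TPM with a pseudocount of 1 but 603 with 0.01, so most of that fall goes with the pseudocount, 1000 from 50 counts and 281 from 1000, and 90.7% to 93.5% were lower in replicate 2. The top isoform was shared by 95% from 5 TPM and 97.3% where it held 50 percent. The mm9 correlation was 0.939 (pseudocount 0.1) and 0.850 (reproducible genes). The other causes were not tested. Between 23 and 24 lists lay outside their range. Of 272 list shifts 8 came inside and 7 went outside, and of 1025 named gene ratios 13 fell short of 2-fold and 2 reached it. Inside the range, the median of synapses changed sign under spike-in scaling, and that of glutamate transport under DESeq2 and spike-in scaling and in TPM with either pseudocount, all near 0. Of 234 counts of detected members 18 moved, mostly in the lower mm9 RPKM, and of 66 exon inclusion values from a single junction 37 moved by more than the SD between fields, among the named exons that of Pax6, to 19.1%. Depth limits the ratios of genes with few counts.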

Other observations

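All exon inclusion values, and the tests of library scaling, of a longer cord and of a higher neural share, were chosen after the results were seen; the other tests were chosen before their own values were seen, on gene lists written after the patterns. Splice junction reads on mm9 gave exon use in several neural genes at this single age, as the share of reads that include an exon rather than skip it (mean ± SD over 2 fields, which are not assigned to replicates). The 93-nucleotide exon of Mapt (chromosome 11, 104179471 to 104179563), which encodes a microtubule-binding repeat of tau, was included in 3.21% ± 0.683 (2.72% and 3.69%), with 1875 and 2049 skipping reads. The mm10 transcript tables put 99.3% of coding Mapt TPM in both replicates into the 5 of 8 coding transcripts that carry the exon, and the other 3 have at most 6 exons. App, the amyloid precursor gene, included its 168-nucleotide exon (chromosome 16, 85043821 to 85043988) in 24.0% and 14.4% and its 57-nucleotide exon in 13% and 6.47%, differences between fields beyond the exact intervals (22.9% to 25.2% and 13.6% to 15.3% for the first). The 34-nucleotide exon of the neuronal splicing factor Ptbp2 was included in 94.0% ± 1.73, the 42-nucleotide exon of Pax6 in 20.9% ± 1.80, and a 33-nucleotide exon of Numb, an inhibitor of Notch, in 36.3% and 15.8%. A first filter required inclusion of at least 5 percent and was dropped after a first look, so that mostly skipped exons stayed in.

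The field numbers of the mm9 tables run in opposite order to each other. Across 13773 genes, the log2 ratio of field 2 over field 1 in the mm9 gene table correlated with the mm10 log2 ratio of replicate 2 over replicate 1 at Pearson r = -0.929, and the same ratio from the junction table at 0.973 over 12218 genes. Xist had 0.0163 and 39.8 RPKM in fields 1 and 2 of the gene table, and 7235 and 16 reads in fields 1 and 2 of the junction table. In the mm10 tables, 33 genes had 0 TPM in one replicate and at least 5 TPM in the other, and 31 of them were shorter than 200 nucleotides. The small nucleolar RNA gene Gm22988 had 89 and 206 counts but 0 and 1420.4 TPM, with effective lengths of 0 and 1.72 nucleotides.

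Muscle, cartilage and epithelial genes were higher in replicate 1, and the design, with a single group, names no biological difference to set against the explanations tested here and for the patterns that follow. Library scaling is argued against, since scaled to the spike-ins the median log2 ratio of the 32 members was still -3.77. Non-neural tissue left on the dissected nervous system may be a source: 15 genes of the inner ear and face whose values had not been seen had a median of -1.18 (8 at least 2-fold lower in replicate 2), and 9 genes of trunk and limb mesoderm had -1.25 (5 at least 2-fold lower). The medians do not separate head from trunk tissue, and an earlier test on their difference was replaced before these were run because it repeated the pattern. Among the most abundant members, Col2a1 still had 73.5 TPM and Actc1 3.26 TPM in replicate 2, and 9 of the 15 and 5 of the 9 tested genes had at least 1 TPM there.

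Of 7 Hox genes of groups 7 to 9 with at least 50 counts, all but Hoxd8 were higher, and those of groups 1 to 3 were lower in replicate 2. A higher share of neural tissue is argued against, since groups 7 to 9 lay 3.86 log2 units above the neurons list while groups 1 to 3 lay below it (-0.69 and -0.01). All 9 trunk mesoderm genes tested were lower in replicate 2 (median -1.25), which argues against more of this tissue there than in replicate 1. Since muscle, cartilage and epithelial genes were also higher in replicate 1, this cannot exclude some trunk mesoderm in replicate 2. A cord that extended further down the trunk in replicate 2 may be a source, but no test here supports it: over the 10 genes of groups 4 to 6 the log2 ratio was higher at higher paralog number (Spearman rho = 0.719), which restates the pattern, since these values, with Hoxc6 among the highest, had been seen. Other values run against more cord: the hindbrain and cord list was lower in replicate 2 (median log2 ratio -0.46, 12 of 16 genes below 0), telencephalon genes were higher, and Hoxd8 and Hoxd9 were lower, so the explanation stays open.

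Xist had 122314 counts in replicate 1 and 94 in replicate 2, while the labels give pooled sexes. A failure to count Xist on mm10 is argued against, since the mm9 fields differed 2442-fold. Few or no female embryos in replicate 2 may be the source, but the 6 genes tested that escape X inactivation had a median log2 ratio of -0.15 (percentile 3.89 of matched lists, 6 of 6 below 0), which does not decide it. The Y-linked genes were higher in replicate 2 by log2 ratios of 1.11 to 1.55. Together with the Xist counts, they argue against an equal share of female RNA in the 2 pools. Their direction is a lower female share in replicate 2, where Xist was 1728-fold lower after scaling. These values do not give the absolute share in either pool.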
